A study of Mus musculus with 10 samples.

How the data were processed

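The series holds 10 RNA sequencing libraries of mouse neural tube explants, 5 WT and 5 Ednrb-/-, which the labels call biological replicates. Per the labels' protocols, RNA was extracted with TRIzol and libraries followed standard Illumina protocols. The submitters' processing notes name fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the build mm10, without saying which settings were used. The values used here are FPKM per the file headers, 1 table with 1 column per library, as deposited by the authors. Each column was matched to its sample by the genotype and replicate number in the sample's title, and there were 0 further columns of values per sample. Filters, pooling and the use of strand in counting are not given in the sources used here.

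The gene identifiers and contig names in the table are those of the C57BL/6NJ strain assembly, although the notes name mm10. Of 29596 symbols shared with the GENCODE M21 annotation of mm10, 99.8% lay on the same chromosome and 0 had the same start position. Coordinates are therefore printed as the file gives them and were not converted. The table holds 42465 gene models, of which 1369 are transcripts added by the authors without a gene name, and 0 lie on chromosome Y. A symbol shared by several models was replaced by the identifier.

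FPKM multiplied by the gene length column was, in every library, a whole multiple of a single step for 100% of values within 0.01 of a read. The reads worked back in this way sum to 15970313, 15653480, 16496793, 16522842 and 13856545 in WT replicates 1 to 5 and to 19532570, 13022266, 17891512, 15974370 and 16652715 in Ednrb-/- replicates 1 to 5. The library total by which the authors divided lies between 0.953 and 1.03 times these sums, for a reason that is not given in the sources used here. The 1.27 FPKM of Aim2 in WT libraries rests on 53 to 91 reads, so genes near the filter carry counting noise, and a low FPKM does not show that a gene is off. Pairs of libraries of a genotype had correlations of log2 values between 0.925 and 0.979 and differed by a mean chi-square per gene of between 15.9 and 100.0, where sampling noise alone gives 1, more than a repeat of 1 library would give. Each replicate therefore entered singly.

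The main test was limma 3.58.1 in R 4.3.3, with a linear model of log2(FPKM + 0.5) on genotype, all 10 libraries, no covariate and a prior variance that follows the mean level (limma-trend). Genes entered with an FPKM of at least 0.5 in at least 5 of the 10 libraries. P values are two-sided and adjusted by Benjamini-Hochberg over the 15156 genes tested, with a threshold of 0.05. Fold changes are Ednrb-/- minus WT on the log2(FPKM + 0.5) scale, which understates the change of low genes. The terms rose and fell are used of genes with an adjusted p under the threshold. Ednrb and Aim2 were also tested by an exact two-sided permutation of their mean log2 difference over all assignments of 5 against 5 libraries. The replicate numbers were not taken as pairs.

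Gene lists, 40 in number, were written down before the data were examined for pigment, neural crest, glial, neuronal and other cell types that explants can hold, for axial identity, for signalling, stress and immune pathways and for RNA quality. Of their 806 symbols 734 were found in the table. The 36 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists. Of these, 21 passed, 2 upward and 19 downward. With a correlation estimated from the data 0 passed (7 at an unadjusted p under 0.05), the lowest adjusted p being 0.212. By fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, 22 passed. The preset therefore carries the list calls, and each call of the main fit is printed with its value under the estimate. Of the alternative fits described below, only that with a smooth muscle covariate was also run with an estimate. The lists of mitochondrially encoded and Y-linked genes had 0 tested genes and are not analysed here. Genes in more than 1 list are counted in each.

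Genes named in the text follow a rule fixed before the data were examined: Ednrb and Aim2, the 12 largest rises and 12 largest falls among protein-coding genes past the threshold whose groups do not overlap, leaving out predicted models, and up to 4 members of each list with the lowest p. Others are said to be named after their values were seen. Some genes that the rule takes are not reported here.

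The fit and the list test were tested on simulated data for this comparison before use. Reads were drawn for the real genes from the real mean levels, library sizes and spread, with 200 genes changed. Of genes changed 1.5-fold, 2-fold and 4-fold, 27.7%, 54.7% and 92.3% were recovered among 15259 genes, and 13 unchanged genes were called beside 113 changed ones. With no change put in, 0 genes and 0 lists were called among 15228 genes. A list whose members were all moved 1.5-fold was called and 0 other lists were. Genes were drawn independently of each other in this simulation. It therefore could not test whether the preset correlation of the list test suits real libraries, in which genes of a list move together.

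Alternatives tried were pseudocounts of 1 and 0.1, no filter, a filter at 1 FPKM, rescaling by median ratios, rescaling to TPM, quantile normalization, a prior variance without trend, a robust prior variance, array weights, a replicate block, protein-coding genes only, limma voom on the recovered reads, and leaving out each library in turn. After the data were examined, fits were added with a covariate for Xist, for the mean of Hox groups 10 to 13 and for the mean of the smooth muscle list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.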

Results

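RNA was sequenced from cultured neural tube explants of mouse embryos taken at embryonic day 9.5. The neural tube is the source of the neural crest, the migratory cells that form pigment cells, peripheral glia, autonomic and enteric neurons and, in the head, connective tissue. The explants, which contained neural crest cells, were either wild type (WT) or Ednrb-/-, with 5 biological replicates of each genotype. They were kept for 4 days in medium with 10% fetal bovine serum and 20 nM EDN3, the peptide ligand of the endothelin receptor type B. Each library was reported as FPKM for 42465 gene models. Reads worked back from those values came to between 13022266 and 19532570 per library. In all, 15156 genes had an FPKM of at least 0.5 in at least 5 of the 10 libraries and were tested. The study's title and design text name the question, which is how the receptor, Aim2 and AKT act on the proliferation of melanoblasts, the precursors of pigment cells. The single comparison of the design is Ednrb-/- against WT.

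Ednrb, the targeted gene, was lower in all 5 Ednrb-/- libraries than in any WT library. In the file it has the identifier MGP_C57BL6NJ_G0022037 and lies on chromosome 14 from 104372554 to 104403009 on the minus strand, in coordinates of the C57BL/6NJ strain assembly that the identifiers name. WT replicates 1 to 5 held 55.6, 55.5, 45.8, 43.8 and 60.7 FPKM, and Ednrb-/- replicates 1 to 5 held 5.89, 11.7, 7.83, 8.01 and 2.34 FPKM. The means were 52.3 ± 7.16 and 7.15 ± 3.41 FPKM (SD, n = 5 each), a log2 fold change of -2.92 with a standard error of 0.31 (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 libraries allow). The Ednrb-/- libraries still held between 161 and 615 reads of the gene, and the labels do not say which part of it was removed.

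Aim2, a sensor of cytosolic double-stranded DNA that can assemble an inflammasome, was higher in all 5 Ednrb-/- libraries than in any WT library, at a low level in both. The gene has the identifier MGP_C57BL6NJ_G0017209 and lies on chromosome 1 from 185258101 to 185386443 on the plus strand of the same assembly. WT libraries held 1.27 ± 0.25 FPKM and Ednrb-/- libraries 2.16 ± 0.36 FPKM (SD, n = 5 each), a log2 fold change of 0.59 with a standard error of 0.16 (exact two-sided permutation p = 0.00794, the smallest possible). These values rest on between 53 and 142 reads per library. By limma over all genes the adjusted p was 0.0244, and it passed 0.05 no longer without WT replicate 4 (0.0668), without WT replicate 5 (0.0663) or without Ednrb-/- replicate 5 (0.0624), nor with no filter on low genes (0.0678). The model of Aim2 overlaps that of Cadm3, a neuronal adhesion gene on the opposite strand, over 16846 bases, and the sources used here do not say whether counting used strand. Cadm3, named after its values were seen, had 24.6 ± 2.35 FPKM in WT and 34.7 ± 7.34 FPKM in Ednrb-/- libraries (limma, log2 fold change 0.47, adjusted p = 0.0393; 0.0866 without WT replicate 3, 0.0922 without WT replicate 4, 0.0927 without WT replicate 5, 0.0827 without Ednrb-/- replicate 2, 0.0950 without Ednrb-/- replicate 3 and 0.0802 without Ednrb-/- replicate 5).

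Pigment cell genes, contractile genes and matrix genes were among the largest losses in the Ednrb-/- explants, and anterior Hox genes and neuronal genes among the largest gains. In all, 2956 of the 15156 genes changed (limma, Benjamini-Hochberg threshold 0.05), 990 of them higher and 1966 lower in Ednrb-/-. Of these, 1042 changed at least 2-fold, 46 of them upward and 996 downward. Losses were thus larger than gains, while the median log2 fold change over all genes tested was 0.0048. The groups did not overlap in any library for 2004 genes, 13.22% of those tested, where chance gives 0.794%. Under quantile normalization the calls split into 1603 higher and 1730 lower. The count of changed genes fell to 1945 without WT replicate 3, 1960 without WT replicate 4 and 1955 without WT replicate 5. The count of higher genes fell further, to 513, 521 and 514 without those libraries in turn, 586 without Ednrb-/- replicate 3 and 546 without Ednrb-/- replicate 5.

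The 12 protein-coding genes with the largest fall among those whose groups did not overlap were led by Pmel, the fibril protein of melanosomes, from 38.9 ± 29.6 to 1.01 ± 0.51 FPKM. Next was Gpnmb, a melanosomal glycoprotein, from 43.5 ± 16.3 to 2.65 ± 2.79 FPKM (SD, n = 5 each). Their log2 fold changes were -4.30 and -4.15, with standard errors of 0.60 and 0.51. The others were Col1a1 (-3.68), Acta2 (-3.54), Fn1 (-3.41), Myl9 (-3.32), Ctgf (-3.32), Mcam (-3.28), Cdh19 (-3.28), Klhl30 (-3.27), Gprc5a (-3.27) and Tagln (-3.26). They include a collagen I chain, fibronectin and the contractile proteins of smooth muscle and myofibroblasts. Among protein-coding genes whose groups did not overlap, the 12 largest gains were smaller. Hoxc5 rose by a log2 fold change of 1.43, Prph, the intermediate filament of peripheral and motor neurons, by 1.33, Sncg by 1.29 and the zinc finger gene Zfp605 by 1.29. They were followed by Hoxb4 (1.22), Hoxa5 (1.17), Hoxa2 (1.11), Cdo1 (1.09), the motor neuron factor Lhx3 (1.03), the neuronal factor Nhlh2 (1.01), Zfp811 (0.98) and the melanocortin receptor gene Mc5r (0.94).

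**Figure D1:**
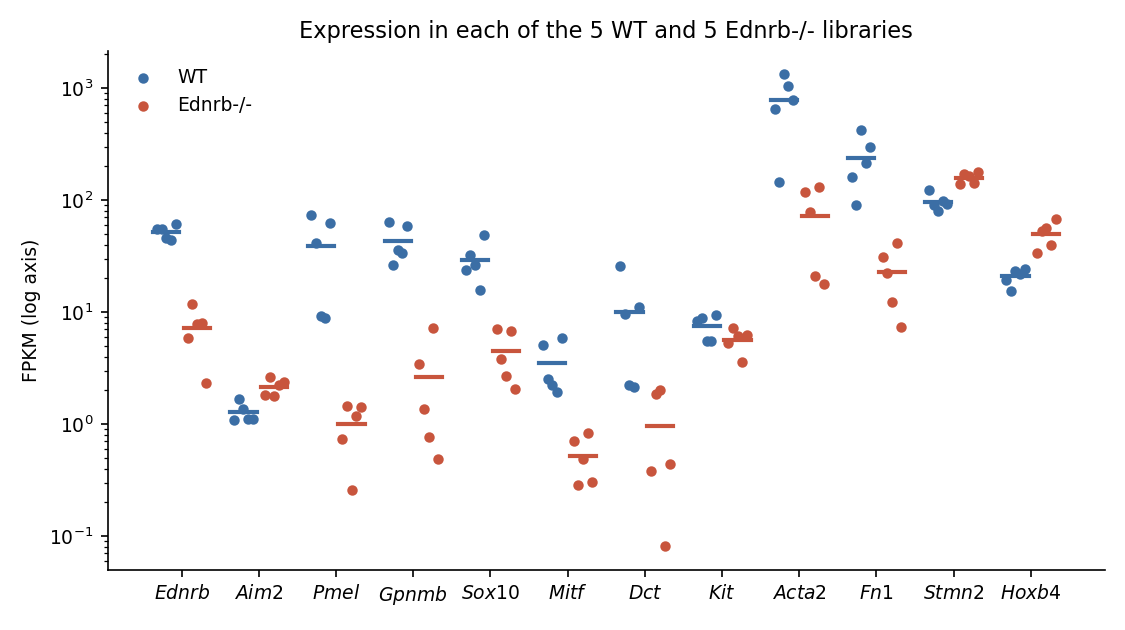
FPKM on a log axis for 12 genes in each of the 5 WT and 5 Ednrb-/- libraries, with points for libraries and bars for group means. The groups are apart for every gene drawn except Kit, whose WT values run from 5.54 to 9.41 and whose Ednrb-/- values run from 3.57 to 7.24 FPKM.

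Melanocyte genes fell as a group. Of the 14 members of the melanocyte lineage list that were tested, 9 fell and none rose (9 adjusted over the list alone), with a median log2 fold change of -1.99 (camera, adjusted p = 4.52e-07; adjusted p = 0.212 with an estimated correlation). Besides Pmel and Gpnmb these included Sox10, the neural crest factor that switches on Mitf, from 29.3 ± 12.2 to 4.48 ± 2.33 FPKM, and Mlph, which tethers melanosomes to actin, with a log2 fold change of -2.39. Named after their values were seen, Mitf, the master regulator of the lineage, fell from 3.55 ± 1.82 to 0.523 ± 0.243 FPKM and Dct, a melanin synthesis enzyme and early melanoblast marker, from 10.1 ± 9.57 to 0.960 ± 0.914 FPKM (SD, n = 5 each). The adjusted p of Dct was 0.0181 by limma-trend and 0.0630 by limma voom on the recovered reads. Kit, the receptor that melanoblasts need to survive and migrate, also named after its values were seen, did not pass, at 7.53 ± 1.85 FPKM in WT and 5.67 ± 1.37 FPKM in Ednrb-/- libraries (limma, adjusted p = 0.218).

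Part of the neural crest list fell too, and the glial list was mixed. In the neural crest specification and migration list 13 of 27 genes fell and none rose (15 fell adjusted over the list alone), among them Ets1 (-2.77), Snai2 (-2.32) and the neuregulin receptor gene Erbb3 (-2.22), all on the log2 scale (camera, adjusted p = 1.56e-05; adjusted p = 0.212 with an estimated correlation). In the list of glia and Schwann cell precursors 7 of 16 genes fell and 1 rose (7 and 2 adjusted over the list alone). Cdh19 fell from 13.3 ± 6.15 to 0.906 ± 0.617 FPKM, and the receptor gene Gfra3 fell by 2.43 on the log2 scale. Fabp7, a lipid-binding protein gene of glia and neural progenitors, named after its values were seen, rose from 268 ± 88.8 to 427 ± 61.5 FPKM (SD, n = 5 each; limma, adjusted p = 0.0384). It passed no longer without WT replicate 3 (0.0580), 4 (0.0793) or 5 (0.0862), without Ednrb-/- replicate 2 (0.0784), 3 (0.0717) or 5 (0.0906), or with no filter (0.0882). The list's median was -0.446 (camera, adjusted p = 0.0356; adjusted p = 0.259 with an estimated correlation), and its adjusted p was 0.0656 without WT replicate 1, 0.0747 without WT replicate 2, 0.0702 without Ednrb-/- replicate 1, 0.0888 with array weights and 0.0545 over protein-coding genes only.

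Genes of smooth muscle, fibroblast-like mesenchyme and extracellular matrix made up the broadest loss. All 11 smooth muscle genes tested fell (11 adjusted over the list alone), with a median log2 fold change of -2.58. Acta2, the smooth muscle actin, went from 784 ± 442 to 72.6 ± 52.2 FPKM (SD, n = 5 each). In the fibroblast-like mesenchyme list 12 of 14 genes fell and 1 rose (13 and 1 adjusted over the list alone). Col5a1 and the microfibril gene Fbn1 fell by 2.66 and 2.49 on the log2 scale. Dcn, the matrix proteoglycan decorin and the member that rose, named after its values were seen, went from 6.72 ± 2.80 to 44.2 ± 32.2 FPKM. In the list of basement membrane and matrix remodelling 19 of 23 genes fell and none rose (20 fell and 1 rose adjusted over the list alone), including the gelatinase gene Mmp2, its inhibitor gene Timp2, the protease gene Adamts1 and the perlecan gene Hspg2, at log2 fold changes of -2.55, -1.37, -2.45 and -3.18. The camera adjusted p values of the lists were 9.92e-08, 1.88e-06 and 7.50e-10, and with an estimated correlation each adjusted p = 0.259. The medians of the fibroblast-like and matrix lists were -2.25 and -2.14, and -0.16 and -0.25 with the smooth muscle mean as a covariate, chosen after seeing the data (camera, adjusted p = 0.352 and 0.198). These genes also differed among libraries of one genotype. The mean log2(FPKM + 0.5) of the smooth muscle list ran from 3.19 in WT replicate 2 to 5.56 in WT replicate 3, and from 1.46 in Ednrb-/- replicate 5 to 3.11 in Ednrb-/- replicate 4.

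Cartilage and bone genes and the few epithelial genes tested were also lower. In the cartilage and bone list 5 of 11 genes fell and none rose (6 fell and 1 rose adjusted over the list alone), among them Runx2, a bone lineage factor, and Col2a1, the main cartilage collagen, with log2 fold changes of -1.84 and -2.24 (camera, adjusted p = 0.00243; adjusted p = 0.259 with an estimated correlation; 0.164 with the mean of Hox groups 10 to 13 as a covariate, chosen after seeing the data). Of 5 epithelial and surface ectoderm genes, 4 fell (4 adjusted over the list alone), including the keratin genes Krt19 and Krt18, with log2 fold changes of -3.21 and -2.79 (camera, adjusted p = 0.00433; adjusted p = 0.212 with an estimated correlation). The list's median was -2.79, and -0.47 with no filter (camera, adjusted p = 2.27e-06).

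**Figure D2:**
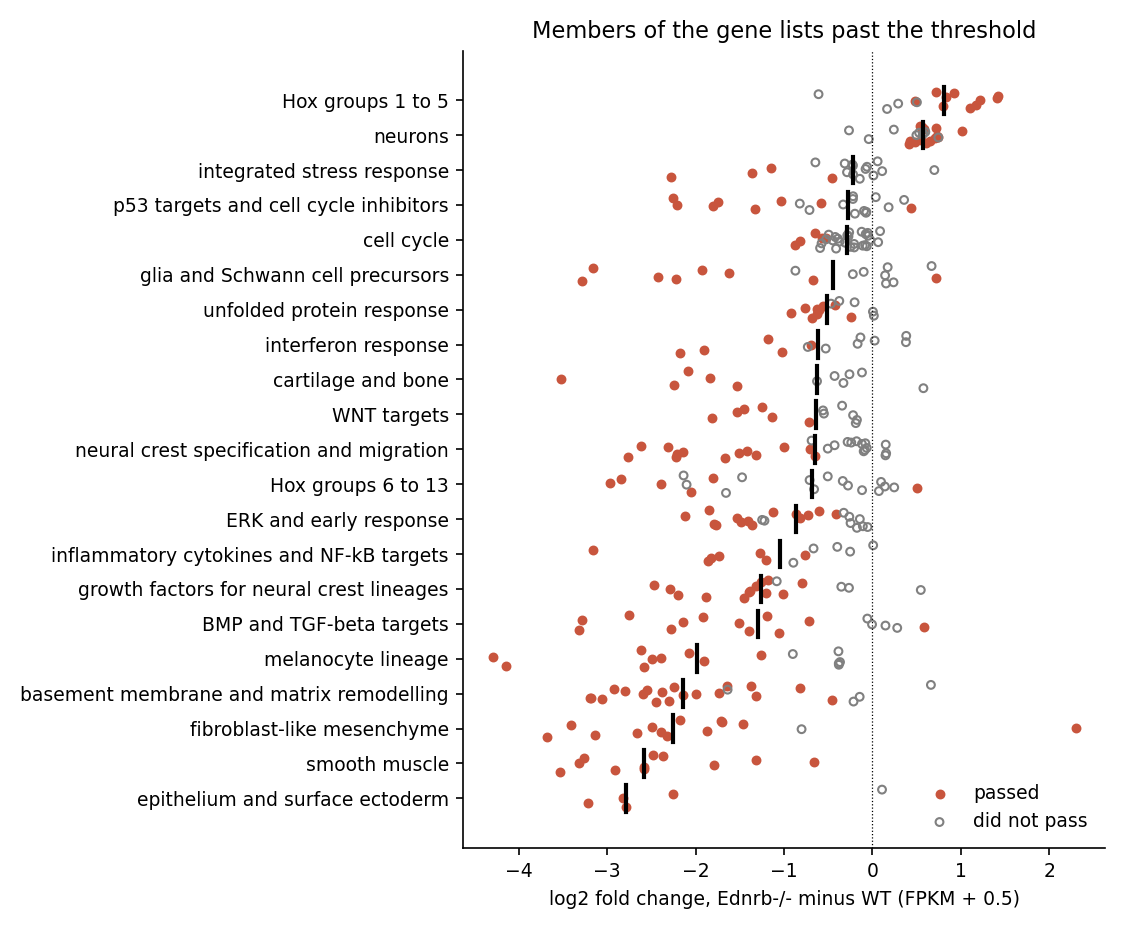
Log2 fold change (Ednrb-/- minus WT) of each member of the 21 gene lists past the threshold. Filled points passed limma's threshold over all genes, open points did not, and black bars are list medians, which run from -2.79 for epithelium and surface ectoderm to 0.81 for Hox groups 1 to 5.

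Neuronal genes rose by smaller amounts. In the neuron list 14 of 23 genes rose and none fell (15 rose adjusted over the list alone), with a median log2 fold change of 0.57 (camera, adjusted p = 2.31e-09; adjusted p = 0.212 with an estimated correlation). With the smooth muscle mean as a covariate, chosen after seeing the data, the median was 0.35 (camera, adjusted p = 1.66e-05, and 0.319 with an estimated correlation). The neuronal RNA-binding protein genes Elavl2 and Elavl4 rose from 30.3 ± 3.40 to 46.3 ± 2.45 FPKM and from 50.3 ± 6.95 to 79.1 ± 9.06 FPKM, and Stmn2, a growth cone protein, from 96.5 ± 16.1 to 158 ± 17.3 FPKM (SD, n = 5 each). The list of autonomic and enteric neuron progenitors, in which Prph rose and 1 of 13 genes fell, did not pass (camera, adjusted p = 0.0530). It passed without WT replicate 2 (0.0131), without WT replicate 5 (0.0267) and without Ednrb-/- replicate 4 (0.0294). It also passed under TPM rescaling (0.0440), without a trend in the prior variance (0.0465) and with array weights (0.0317).

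Among neural tube progenitor genes, members moved in opposite directions. Of 24 tested, 1 rose and 3 fell (1 and 2 adjusted over the list alone). Nkx6-2, a factor of the ventral tube, rose from 6.68 ± 3.83 to 14.7 ± 3.79 FPKM. Lmx1a, a factor of the dorsal roof plate, fell from 4.45 ± 1.01 to 1.18 ± 0.918 FPKM, and the progenitor filament gene Nes fell from 86.3 ± 15.05 to 59.4 ± 5.99 FPKM (SD, n = 5 each). The list as a whole did not pass (camera, adjusted p = 0.0592), though it did without WT replicate 2 (0.0042), without WT replicate 5 (0.0256), without Ednrb-/- replicate 1 (0.0390) and without Ednrb-/- replicate 5 (0.0483). It also passed with no filter (0.00963), under TPM rescaling (0.0440) and with array weights (0.0317).

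**Figure D3:**
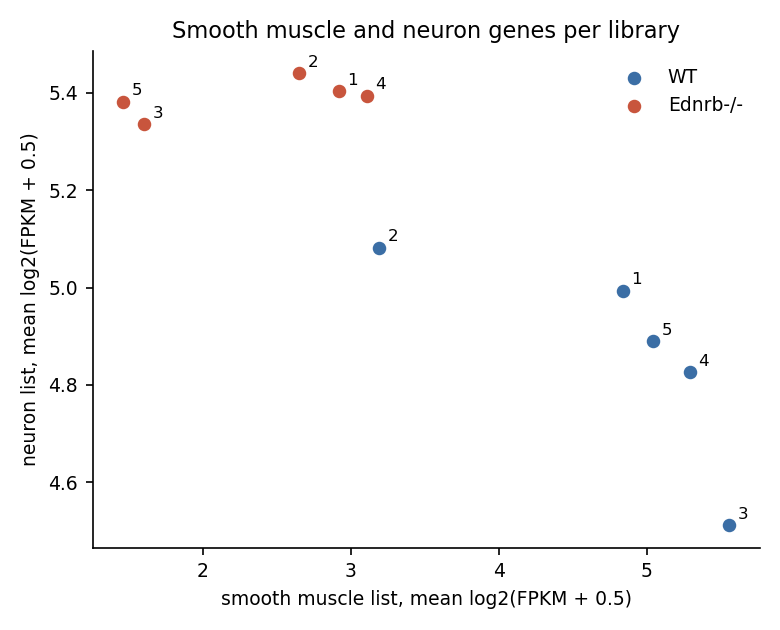
Mean log2(FPKM + 0.5) of the neuron list against that of the smooth muscle list, 1 point per library, numbered by replicate. WT libraries lie between 3.19 and 5.56 on the smooth muscle axis and Ednrb-/- libraries between 1.46 and 3.11, with every Ednrb-/- library above every WT library on the neuron axis.

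Hox genes, which mark position along the body axis, changed by paralogous group. In groups 1 to 5, expressed from the hindbrain and neck downward, 10 of 14 genes rose and none fell (11 rose adjusted over the list alone), with a median log2 fold change of 0.81 (camera, adjusted p = 7.19e-07; adjusted p = 0.243 with an estimated correlation). Hoxd3 went from 5.84 ± 0.638 to 11.6 ± 2.08 FPKM and Hoxc4 from 53.4 ± 7.02 to 95.9 ± 15.7 FPKM (SD, n = 5 each). In groups 6 to 13, expressed in trunk and tail, 1 of 20 genes rose and 5 fell (1 and 7 adjusted over the list alone), with a median of -0.68 (camera, adjusted p = 0.0106, and 0.0629 without Ednrb-/- replicate 2; adjusted p = 0.520 with an estimated correlation; fry, adjusted p = 0.0993). The falls were in the 8 genes of groups 10 to 13 that were tested, with a median of -2.08, among them Hoxc12 (-2.97), Hoxc11 (-2.39), Hoxa11 (-2.05) and Hoxd11 (-1.80). None of the 8 is of group 13, whose genes lay below the filter. Named after their values were seen, Hoxa13, Hoxb13, Hoxc13 and Hoxd13 had 4.32, 17.5, 13.6 and 4.71 FPKM in WT replicate 2. Their highest value in any other library was 1.32 FPKM, that of Hoxc13 in WT replicate 3. The 12 genes of groups 6 to 9 had a median of -0.196. Hoxc12 was listed at 0 in 4 Ednrb-/- libraries and at 0.656 FPKM in replicate 4.

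**Figure D4:**
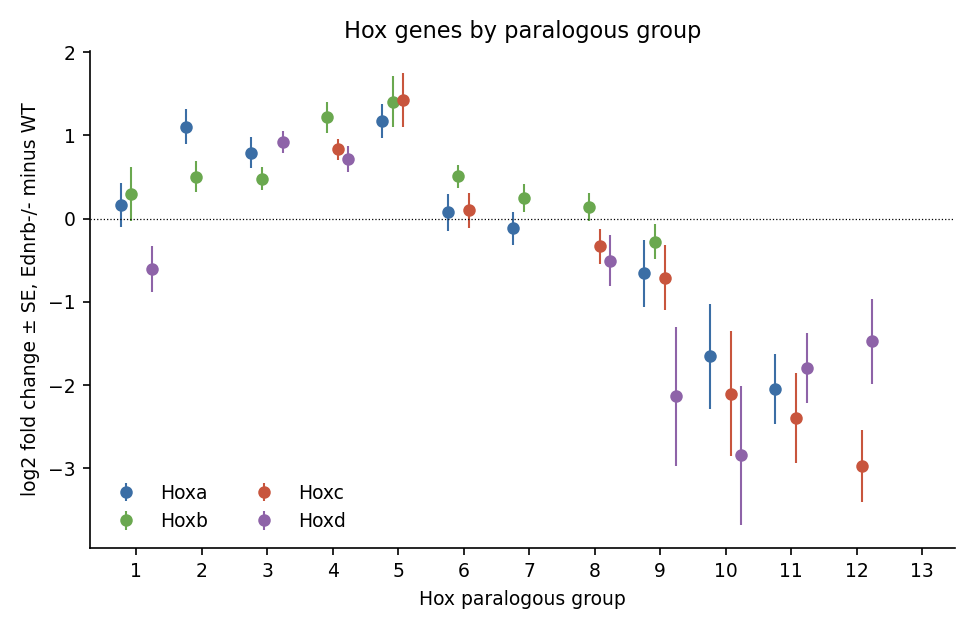
Log2 fold change (Ednrb-/- minus WT) of 34 Hox genes by paralogous group and cluster, with bars of 1 standard error. Values lie mostly above 0 up to group 5 and at or below -1.47 from group 10 on.

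The ERK, growth factor, WNT, and BMP and TGF-beta lists moved downward by camera at the preset correlation. In the list of ERK and early response genes 14 of 23 fell and none rose (18 fell adjusted over the list alone), including Etv5, Spry4 and Dusp6, which growth factor signalling induces, at log2 fold changes of -1.41, -1.84 and -1.77 (camera, adjusted p = 1.40e-08; adjusted p = 0.212 with an estimated correlation). The list's median was -0.87, and -0.29 with the smooth muscle mean as a covariate, chosen after seeing the data (camera, adjusted p = 0.0101, and 0.418 with an estimated correlation). Among growth factors for neural crest lineages 13 of 17 fell and none rose (14 fell adjusted over the list alone). Igf2 went from 39.9 ± 3.14 to 15.98 ± 6.96 FPKM and Gdnf from 1.66 ± 0.46 to 0.323 ± 0.174 FPKM (camera, adjusted p = 4.98e-07; adjusted p = 0.212 with an estimated correlation). These genes moved with the smooth muscle markers: with that covariate the list's median was -0.15, against -1.26 without it (camera, adjusted p = 0.106). WNT targets fell in 6 of 12 genes and rose in none (6 adjusted over the list alone), with Dkk1, Tcf7 and Lef1 at -1.81, -1.45 and -1.13 (camera, adjusted p = 6.51e-05; adjusted p = 0.259 with an estimated correlation). BMP and TGF-beta targets fell in 11 of 16 genes and rose in 1 (11 and 1 adjusted over the list alone), with the inhibitory gene Smad6 at -1.92 (camera, adjusted p = 0.000567; adjusted p = 0.296 with an estimated correlation). With that covariate the median of the list was -0.14 (camera, adjusted p = 0.974).

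The PI3K-AKT-mTOR list did not move one way, with 2 of 30 genes higher and 6 lower (2 and 6 adjusted over the list alone) and a median log2 fold change of -0.058 (camera, adjusted p = 0.127; 0.0299 without WT replicate 1). Eif4ebp1, a translation repressor that mTOR inactivates, fell from 36.2 ± 8.28 to 10.1 ± 3.40 FPKM, and the AKT-regulated factors Foxo1 and Foxo4 fell by 1.76 and 0.74 on the log2 scale. Akt1, named after its values were seen, fell from 93.9 ± 5.38 to 77.3 ± 5.14 FPKM (SD, n = 5 each; limma, adjusted p = 0.0236). Its adjusted p was 0.0537 without WT replicate 3, 0.0627 without WT replicate 4, 0.0542 without WT replicate 5 and 0.0632 without Ednrb-/- replicate 5. These are RNA levels, and the activity of the kinases was not measured in these files.

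Of the cell cycle list 5 of 31 genes fell and none rose (4 fell adjusted over the list alone), beside 1966 of the 15156 genes tested that fell. Its median log2 fold change was -0.28 (camera, adjusted p = 0.000423; adjusted p = 0.517 with an estimated correlation; fry, adjusted p = 0.0863). It was -0.75 with the smooth muscle mean as a covariate, chosen after seeing the data (camera, adjusted p = 7.08e-19, and 0.319 with an estimated correlation). Cdk2 and its partner cyclin gene Ccne1, which drive entry into S phase, fell from 23.6 ± 2.89 to 13.17 ± 1.503 FPKM and from 10.8 ± 1.60 to 5.70 ± 1.18 FPKM. The replication helicase gene Mcm4 fell from 30.4 ± 3.91 to 21.1 ± 3.59 FPKM (SD, n = 5 each). The list of p53 targets and cell cycle inhibitors was mixed. In it 7 of 20 genes fell and 1 rose (7 and 1 adjusted over the list alone), with the death receptor gene Tnfrsf10b, Cdkn2a and Cdkn1a at log2 fold changes of -2.25, -1.81 and -1.33 (camera, adjusted p = 0.0130; adjusted p = 0.372 with an estimated correlation). The gene that rose, named after its values were seen, was Cdkn1b, itself an inhibitor of cyclin-dependent kinases, from 17.7 ± 1.74 to 24.4 ± 4.11 FPKM (SD, n = 5 each). Its adjusted p by limma was 0.0202, and 0.0540 without WT replicate 3 and 0.0571 without WT replicate 5. With that covariate the median of the p53 list was 0.059 (camera, adjusted p = 0.821), and with the mean of Hox groups 10 to 13 its adjusted p was 0.126.

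Stress and immune lists were lower or mixed. Of 14 unfolded protein response genes 9 fell and none rose (11 fell adjusted over the list alone), among them Manf and the chaperone gene Hspa5 at -0.76 and -0.62 (camera, adjusted p = 3.17e-05; adjusted p = 0.259 with an estimated correlation). In the integrated stress response 4 of 17 fell and none rose (4 adjusted over the list alone), led by Atf3 at -2.28 and Cebpb at -1.37 (camera, adjusted p = 0.0356; adjusted p = 0.259 with an estimated correlation; 0.140 with array weights, 0.0588 by voom, 0.0545 over protein-coding genes only, 0.108 without WT replicate 1, 0.0608 without Ednrb-/- replicate 2 and 0.0825 without Ednrb-/- replicate 4). Of 12 inflammatory and NF-kB genes 7 fell and none rose (8 fell adjusted over the list alone), including Csf1 and Icam1 at -1.86 and -1.83 (camera, adjusted p = 8.71e-05; adjusted p = 0.259 with an estimated correlation). With the smooth muscle mean as a covariate the medians of the unfolded protein, inflammatory and interferon lists were -0.15, -0.097 and -0.19 (camera, adjusted p = 0.0657, 0.925 and 0.821). In the interferon response list 5 of 12 fell and none rose (6 fell and 1 rose adjusted over the list alone), with Gbp2 at -1.90 and the RNA sensor gene Ddx58 at -1.02. Its adjusted p was 0.0473 by camera (adjusted p = 0.372 with an estimated correlation), and it passed 0.05 no longer without WT replicate 1 (0.0617), 3 (0.0555), 4 (0.0623) or 5 (0.0641), or without Ednrb-/- replicate 1 (0.0901), 3 (0.0545) or 5 (0.0587), nor at a filter of 1 FPKM (0.305), a pseudocount of 0.1 (0.0556), TPM rescaling (0.0577), quantile normalization (0.0884) or over protein-coding genes only (0.0547). Of the 37 genes written down for cytosolic DNA sensing and inflammasomes, 5 were tested, of which Aim2 rose and Tmem173, the adaptor STING, fell from 1.66 ± 0.528 to 0.216 ± 0.280 FPKM (1 and 1 adjusted over the list alone). Il18 and Gsdmd, products downstream of an inflammasome, did not pass (limma, adjusted p = 0.435 and 0.284), and Casp1 and the adaptor gene Pycard, named after their values were seen, had group means of 0.453 and 0.332 FPKM in WT and 0.0396 and 0.139 FPKM in Ednrb-/- libraries, below the filter (camera for the list, adjusted p = 0.848).

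In the endothelin system itself 2 of 4 genes tested fell (2 adjusted over the list alone, where 1 also rose). They were Ece1, the converting enzyme, from 17.1 ± 5.32 to 6.04 ± 2.00 FPKM, and the ligand gene Edn1, from 2.01 ± 1.02 to 0.544 ± 0.272 FPKM. The receptor gene Ednra had 1.14 ± 0.141 FPKM in WT and 2.01 ± 0.798 FPKM in Ednrb-/- libraries (limma, adjusted p = 0.118, and 0.0420 without Ednrb-/- replicate 5; camera for the list, adjusted p = 0.302). Edn3, named after its values were seen, had group means of 0.0466 and 0.0350 FPKM, below the filter.

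The remaining lists did not pass by camera. Adjusted p values were 0.0684 for MHC class I, in which B2m fell by 1.16 on the log2 scale, 0.0993 for cholesterol synthesis, 0.139 for replication-dependent histones, 0.194 for skeletal muscle, in which Acta1 fell by 2.72, and 0.2504 for endothelium, in which Kdr fell by 1.79. They were 0.553 for apoptosis, in which Casp8 fell by 1.68 and the pro-death gene Hrk rose by 0.93, 0.757 for heat shock, 0.774 for the Notch pathway, 0.786 for hypoxia and glycolysis and 0.848 for cranial neural crest and midbrain-hindbrain identity. For the Notch pathway the median was 0.07 and the mean -0.04 with the test upward, and for cranial identity the median was 0.12 and the mean -0.28 with the test downward. Without single libraries 2 of these passed. MHC class I did so without WT replicate 2 (0.0379) and without Ednrb-/- replicate 3 (0.0400), and cholesterol synthesis without WT replicate 2 (0.0379) and without Ednrb-/- replicate 4 (0.000817). With no filter both passed (0.0084 and 0.0209), MHC class I also under quantile normalization (0.0464) and cholesterol synthesis with array weights (0.0144). The macrophage and erythroid lists had 1 tested gene each, and their summed FPKM was 2.67 ± 0.651 and 1.498 ± 0.403 in WT against 1.66 ± 1.01 and 1.48 ± 0.237 in Ednrb-/- libraries (SD, n = 5 each).

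Libraries of a genotype were not uniform. The first principal component held 47.5% of the variance and separated the genotypes, with WT libraries between -60.7 and -6.09 and Ednrb-/- libraries between 4.64 and 53.8. Of all pairs of a WT and an Ednrb-/- library, WT replicate 2 and Ednrb-/- replicate 4 lay nearest to each other on it. Ednrb-/- replicate 2 stood apart on the second component, which held 13.97%, at -60.1. Xist, the RNA of the inactive X chromosome, named after its values were seen, was at 1.33 FPKM in WT replicate 4 and at 0.844 and 2.51 FPKM in Ednrb-/- replicates 1 and 5, and between 25.2 and 74.3 FPKM in the other 7 libraries.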

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

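The tests of an outgrowth cell share, of the Hox trend, of Hox against smooth muscle genes, of Cadm3 reads and of macrophages were chosen only after the result was seen, as was the margin of 1 standard error in the tests of macrophages and of axial level on smooth muscle genes. A search for a library far from the other 4 of its genotype covered 218 groups of values, found 12 and would find about 10.9 by chance (1 in 20). In Ednrb-/- replicate 4, Mlph was at 0.481 FPKM (others 0.0236 to 0.142), Cdkn1a at 46.93 (23.5 to 28.8), Krt19 at 4.803 (0.444 to 1.47), Hoxa11 at 1.478 (0 to 0.309), Hoxc11 at 2.493 (0 to 0.450) and Hoxc12 at 0.6556 (all at 0), each nearer to the WT level than the other Ednrb-/- libraries. In WT replicate 2, Hoxc12 was at 12.47 FPKM (1.78 to 4.41) and B2m at 51.92 (121 to 147). In WT replicate 5, Nkx6-2 was at 13.33 FPKM (3.77 to 6.30). Zfp811 was at 28.35 FPKM in WT replicate 1 (17.9 to 20.3) and Krt18 at 25.29 FPKM in WT replicate 4 (6.32 to 11.6). On the second principal component Ednrb-/- replicate 2 scored -60.11 (11.7 to 25.2). Chance is argued against for the count of changed genes, though not excluded. Of 100 splits of the 10 libraries drawn from 126, 1, the real one, called as many as 2956, and the highest other called 1348. That other split exchanged WT replicate 2 and Ednrb-/- replicate 4, which of all pairs across genotypes lie nearest on the first principal component.

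Smooth muscle, fibroblast-like and matrix genes were lower and neuronal genes higher in Ednrb-/- explants. Library scaling is argued against, since over 3 other scalings the neuron median stayed at or above 0.5699 and the smooth muscle median at or below -2.445, and so is gene length, since with its trend removed the smooth muscle median was -2.462 and the neuron median 0.685. A smaller share of non-neural outgrowth cells is a candidate explanation: across 60 genes, which are not independent replicates, the slope on the smooth muscle mean within genotypes correlated with the genotype change at r = -0.947, the sign this explanation needs because that mean is lower in the mutants (the sign was first written the wrong way round and was corrected after the result was seen). That r cannot tell a smaller share of such cells from lower levels of these genes within the same cells. Among the 23 neuron genes alone r was -0.113, and their slope predicts a rise of 0.191 where 0.57 was seen, so the neuronal rise may have a further source. A different axial level as the whole source stays open. With the Hox 10 to 13 mean as a covariate the smooth muscle median was -2.692. The difference in the smooth muscle mean was -2.34 with a standard error of 0.97 (-2.44 with 0.539 without the covariate). That is below the bound of -1 by more than 1 standard error but not by 2, the margin first used (-0.40). The covariate also follows genotype (r = -0.805) and holds no gene of group 13. Its highest value in Ednrb-/- libraries, 1.82, lay below its lowest in WT libraries, 1.93. It ran against the smooth muscle mean in WT and with it in Ednrb-/- libraries, whereas the fit gave both genotypes a common slope. The fit therefore cannot decide on axial level. Genotype itself, which the design names, stays open too.

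Hox groups 1 to 5 were higher and groups 10 to 13 lower. A difference in axial level between the WT and Ednrb-/- explants cannot be told apart from other sources: the fall of the change with the Hox group number (Spearman rho = -0.777 across 34 genes) restates the pattern and supports none of them, and the labels used here do not give the level at which tubes were cut. Loss of smooth muscle and matrix cells cannot be told apart as a source of the fall in groups 10 to 13: within genotypes the means of both gene groups had r = 0.0485 (exact permutation p = 0.888; rank correlation 0.12, exact p = 0.748). It was 0.346 without the 2 libraries farthest on the smooth muscle axis. The pooled r joins relations that ran opposite ways and does not show that the means are unrelated. In WT, replicate 2 had the highest Hox mean (3.54) and the lowest smooth muscle mean (3.19), and replicate 3 the reverse (1.93 and 5.56). In Ednrb-/-, replicate 4 had the highest of both (1.82 and 3.11) and replicate 5 the lowest of both (-0.41 and 1.46). An effect of genotype on Hox genes was not tested apart from these.

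Aim2 was higher in Ednrb-/- explants. Macrophages in the mutant libraries are argued against, since the summed FPKM of the 19 macrophage genes was not higher but lower by 1.01 there, with a standard error of 0.537 (1.66 in Ednrb-/- and 2.67 in WT libraries, whose ranges overlap; exact permutation p = 0.0873; 0.447 and 1.09 without Cd68, left out after its values were seen, p = 0.0397). Reads of the overlapping gene Cadm3 cannot be told apart, because the log2 ratio of Aim2 to Cadm3 was higher by 0.298 in Ednrb-/- libraries with an exact permutation p of 0.127, although the mm10 annotation has 0 overlapping exon pairs for them. A larger neuronal share of the RNA cannot be told apart either, since with the neuron list mean as a covariate the log2 fold change of Aim2 was 0.476 with a standard error of 0.353 (unadjusted limma p = 0.206; 0.589 with 0.159 before), and that mean follows genotype (r = 0.884). An effect of the receptor on Aim2 itself stays open.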

How the results depend on the processing

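Of 103 named results 98 were called, with Ednrb and Aim2 each entered both by permutation and by limma and the rest by limma alone. Of the 98, 5 were lost on leaving out 1 library and 10 under another planned setting. Aim2 counts among the 10 under both entries, since the replicate block gave it only a limma value. All 98 lost their call under at least 1 covariate chosen after seeing the data. Counts of changed genes moved over 1.5 times as follows, and the cause was not tested: genes higher in Ednrb-/- were 659 with no filter, 1603 with quantile normalization and 1684 with array weights, against 990. Leaving out 1 library gave 1945 to 3276 changed and 513 to 1150 higher genes, with fewer samples in each fit. The replicate numbers do not pair the samples (r of same-numbered libraries -0.163 to 0.153, 1 of 5 best with its own number); with the number as a replicate block 1877 genes changed, 419 of them higher, and Aim2, whose fold of 0.5893 such a block cannot change, lost its call with a limma adjusted p of 0.0666 (0.00644 to 0.765 over all alternatives). With the block the autonomic (0.0262), neural tube (0.0262) and cholesterol (0.0463) lists passed by camera and the glial list did not (0.0503), and by limma Mcm4 (0.0696), Edn1 (0.0613), Ddx58 (0.0509), Akt1 (0.105), Cadm3 (0.0841), Cdkn1b (0.0792) and Fabp7 (0.0697) no longer passed. With an estimated correlation 0 lists passed by camera (7 at an unadjusted p under 0.05), and with fry 22. Of the list results under alternatives, 805 were the same, 38 weaker, 28 stronger and 25 reversed. Medians of called lists moved over 1.5 times and kept their call with no filter, which adds low genes: melanocyte -1.24, fibroblast-like -1.355, cartilage and bone -0.3271, epithelium -0.4697, interferon -0.1345 and inflammatory -0.5165. Cartilage and bone had -1.078 at FPKM 1 and -0.34 with quantile normalization, p53 targets -0.1666 with quantile normalization and interferon -0.9537 by voom. With the Hox covariate such moves were neural crest -0.4146, fibroblast-like -1.351, epithelium -1.82, WNT -0.4074 and Hox 1 to 5 0.3406, and with the smooth muscle covariate glia -0.2966, neurons 0.3488, epithelium -1.444, cell cycle -0.7494 and ERK -0.2932. Robust variance gave no list value, since camera has no such option, and a covariate gives none for the genes and lists it is made of.

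With the Hox 10 to 13 mean as a covariate 0 genes changed, 0 higher, 0 lower and 0 at least 2-fold by limma (2461 at an unadjusted p under 0.05), Ednrb had -2.649 (limma adjusted p = 0.149) and Aim2 0.5815 (0.349). By camera 18 lists passed there, counting Hox 6 to 13, which shares the covariate's genes; cartilage and bone (0.164), p53 (0.126), glia (0.214) and interferon (0.129) were lost and neural tube progenitors gained (0.00377). With the smooth muscle mean as a covariate these counts were again 0 (1152 unadjusted), and by camera 13 lists passed. Lost were fibroblast-like, matrix, growth factor, inflammatory, interferon, unfolded protein and Hox 6 to 13, beside BMP and p53, which turned. Gained were hypoxia (-0.704, camera adjusted p = 4.03e-05) and cholesterol, turned downward (0.001003). With an estimated correlation the lowest adjusted p of any list in that fit was 0.319, and hypoxia and cholesterol had 0.548 and 0.589. Ednrb had -2.503 (limma adjusted p = 0.611) and Aim2 0.3832 (0.765). Both covariates follow genotype (r = -0.805 and -0.848), and neither overlaps between the genotypes. With the smooth muscle mean the standard error of Ednrb went from 0.312 to 0.588 and its fold from -2.92 to -2.50, whereas for Col1a1 the fold itself went from -3.68 to 0.10, with a standard error of 0.748 before and 0.493 after. In the fit with Xist as a covariate 2636 genes changed by limma, 827 higher and 1809 lower. By camera the glial (adjusted p = 0.0641) and interferon (0.0626) lists no longer passed in that fit, and neural tube progenitors did (0.034).

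The direction of the list test turned as follows, values being median log2 fold changes, whose sign can differ from that of the test; the cause was not tested. Cranial identity had 0.215 at FPKM 1, 0.1594 with array weights, 0.1211 with the block, and 0.04309 to 0.1804 over fits without 1 library. Hypoxia had 0.1568 with array weights and -0.1696 to 0.1855 over fits without 1 library. Over such fits cytosolic DNA sensing ran from -0.2092 to 0.08327 (turned at -0.04337 and -0.029), Notch from 0.01239 to 0.1475 (turned at 0.01369) and heat shock from -0.1072 to 0.01488 (turned at -0.0268). With the Hox covariate cytosolic DNA sensing had 0.2842 and Gsdmd 0.09375. With the smooth muscle covariate the lists had -0.1081 (autonomic), -0.1556 (neural tube), 0.1678 (skeletal muscle), 0.2569 (endothelium), 0.05888 (p53), 0.03337 (apoptosis), -0.0951 (endothelin), 0.3258 (DNA sensing), -0.1383 (BMP), -0.3391 (Notch), -0.3305 (cholesterol) and -0.06083 (histones), and genes 0.1017 (Col1a1), 0.03548 (Cdkn1a), 0.3258 (Gsdmd) and 0.2569 (Kdr). Depth limits genes near the filter, such as Aim2 with 53 to 142 reads.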

Other observations

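The families in this part and the test of genes near Ednrb were chosen only after the genes' results were seen. Collagen and zinc finger genes moved apart. Of 30 tested genes whose symbols begin with Col, 19 fell in Ednrb-/- explants and none rose, with a median log2 fold change of -1.70 (camera, adjusted p = 9.48e-09; adjusted p = 0.660 with an estimated correlation). Of 302 Zfp genes, which encode zinc finger proteins, 68 rose and 8 fell, with a median of 0.205 (camera, adjusted p = 6.17e-07; adjusted p = 0.308 with an estimated correlation). Among transcription factor families, 8 of 16 ETS genes fell and none rose, with a median of -0.513 (camera, adjusted p = 0.00016; adjusted p = 0.203 with an estimated correlation), and 10 of 38 bZIP genes fell and 1 rose (camera, adjusted p = 0.00154; adjusted p = 0.114 with an estimated correlation). These medians kept their sign under median ratio, TPM and quantile scaling. Families of at least 15 genes were tested, 75 by symbol, of which 8 passed, and 9 of transcription factors, of which 3 passed.

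An unnamed transcript model on chromosome 14 from 104417304 to 104425506 on the plus strand, 14.3 kb beyond Ednrb and chosen after its values were seen, had 0 to 0.125 FPKM in WT and 0.913 to 4.77 FPKM in Ednrb-/- libraries (limma, log2 fold change 2.21, adjusted p = 0.00276). Genes linked to the targeted locus were a candidate explanation for changes nearby. Of 29 genes tested within 10 Mb of Ednrb 10 changed, 34.5%, against 19.5% of 15126 others (two-sided Fisher's exact p = 0.0569), which does not decide it. The unnamed model, chosen because it changed, counts among both the 29 and the 10, which raises the share nearby.

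Pigment genes kept their direction with the smooth muscle mean added to the model. That mean follows genotype (r = -0.848) and does not overlap, at 3.19 to 5.56 in WT and 1.46 to 3.11 in Ednrb-/- libraries. The fit therefore compares the genotypes at levels that they do not share. With the smooth muscle mean as a covariate chosen after seeing the data, the log2 fold change of Pmel was -5.15 with a standard error of 1.12, against -4.30 with 0.596 without it, and that of Sox10 was -2.01 with 0.645, against -2.62 with 0.350. The melanocyte list had a median of -1.62 in that fit (camera, adjusted p = 3.05e-06; adjusted p = 0.319 with an estimated correlation), while by limma 0 genes passed over all genes (1152 at an unadjusted p under 0.05).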
